A study of Mus musculus with 24 samples.

How the data were processed

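Pancreatic islets were isolated by collagenase digestion from single female NOD mice, and 300 ng of their RNA was labelled with Cy5. A pool of islet RNA from 6 female NOD.B10 mice of the same age was labelled with Cy3 and hybridised to the same array. Each of the 4 ages had 6 NOD mice, which gave 24 Agilent 4×44K two-color arrays (design 014868). All arrays had the same dye orientation, so a dye effect on a probe was not removed within an age; it drops out of a difference between ages. The labels and the close values of the pool channel were read as 1 pool per age, used on all 6 arrays. Read so, it was 1 control sample per age, and the tests of a ratio against 0 leave out the control's own spread, and a difference between ages includes any difference between their pools.

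The deposited scanner files were made with Feature Extraction 10.7.3.1 and hold, per the file headers, the mean spot intensity of each channel with its background and flags for 45018 spots, of which 1639 were controls. Per the file headers, the scanner software's own log ratio was a log10 value after lowess dye normalization. The deposited value table holds log2 ratios for 22122 entries, of which 22088 were noncontrol probes. Against the scanner log ratio turned to log2 its slope was 1 in every column, r was 0.9998 or higher, and between 99.1% and 99.8% of values lay within 1e-05. Its column medians ran from -0.182 to 0.087, so the columns had not been centred, and the rule by which the authors chose its probes is not stated.

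Values were computed from the spot intensities in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (1.17.8). Signals were background corrected by normexp with an offset of 50, and log2(NOD/pool) was normalized within each array by loess, with control spots given no weight. Spots with an outlier flag in either channel were set to missing, which left 44 missing ratios among the genes tested. Spots of a probe were averaged, and of 41174 probes, 25910 were kept because they were well above background in at least 1 channel on at least 6 arrays. Probes were named by RefSeq accession (27151 probes), by current symbol (4091), by an older symbol (569) or, where none matched, by the name in the files alone (9363). The gene table used for names was on assembly GRCm38.p6, and no coordinate was taken from it. Coordinates are those of the files, on mm9. The probe with the highest mean intensity represented each gene, which gave 18069 genes tested.

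One limma model with a mean per age was fitted to all 24 arrays, with an estimated prior of 2.62 degrees of freedom. The mean ratio of each age was tested against 0, and 4 contrasts between ages and a moderated F test over the 4 ages were made. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its change was at least 2-fold. The F test had no fold floor. Errors of a single age are SDs over its 6 mice; errors of a contrast are the model's standard errors. Where a gene was below background in 1 channel on every array of an age, its ratio is given as a bound ("at least").

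The 28 gene lists were fixed before the data were examined. They covered the beta cell; the alpha, delta, PP and epsilon cell; the acinar cell; the Reg family; the duct cell; the T cell; the B cell; the plasma cell; the macrophage and dendritic cell; the NK cell and cytotoxic genes; the neutrophil; and lymphoid tissue organisation. They also covered the type I interferon response, the interferon gamma response, MHC and antigen presentation, chemokines and receptors, the unfolded protein response, the oxidative stress response, genes immature or disallowed in beta cells, islet autoantigens, cell cycle, the endothelial cell, the stellate cell and fibroblast, the Schwann cell, the erythroid cell, the adipocyte, immediate early and dissociation genes, and adenosine signalling. Some genes stand in more than 1 list, such as Ins1 and Ins2, which are beta cell genes and autoantigens. Lists with at least 3 measured genes were tested with camera of limma, with its preset correlation of 0.01 between genes, adjusted over the lists. The mean ratio of each list per mouse was compared between 20 weeks and 10 days by a two-sided exact permutation test, whose smallest possible p is 0.002165.

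Genes were named by a rule also fixed before the data were examined. It took the 6 highest and 6 lowest called genes per comparison with the same sign in all mice, or, for contrasts, with no overlap between the groups of mice. Names that were only clone or accession names were passed over, and at most 2 antigen receptor segments were named per direction. It also took up to 4 called members of each list, and 33 genes whatever their result, of which 32 were tested (Iapp was not found on the array by name). Single-gene results of 2 of these are not reported here; both genes stay in the fit and in the lists.

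The steps were tested on simulated data of the same size, with 50 changed genes per fold size. For 20 weeks, 0% of genes changed 1.5-fold, 50% changed 2-fold, 100% changed 3-fold and 100% changed 4-fold were called. For 20 weeks against 10 days these shares were 0%, 48%, 98% and 100%. Of 17869 unchanged genes, 1 was called for 20 weeks and 0 for the contrast, where 17 and 7 passed the adjusted p alone. Of 5 shifted lists, 4 and 5 were called. Of 20 lists left in place, 0 and 1 were called. These simulated genes varied independently of each other.

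The arrays lay on 6 slides, and all were scanned on 1 day. A single slide held 10 day and 4 week arrays, and another held 12 week and 20 week arrays, so slide could be a fixed block for those 2 contrasts alone. The alternatives were other normalizations, background corrections, filters, sources of values, probe summaries, spread estimates, call thresholds, slide and replicate blocks, list tests, and leaving out each array in turn. A fit by scan date was not made, because there was 1 scan day. Array number limits the precision of every value.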

Results

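Gene expression was measured in pancreatic islets of female NOD mice, a strain that develops autoimmune diabetes, at 10 days, 4 weeks, 12 weeks and 20 weeks of age, with 6 mice per age. Each array set 1 NOD mouse against a pool of 6 NOD.B10 mice of the same age. NOD.B10 mice carry another haplotype of the major histocompatibility complex (MHC) and served as the healthy controls. The ratios below are log2(NOD/pool), given as mean ± SD over the 6 mice of an age, and above 0 where NOD islets had more. Between 42.3% and 64.6% of probes were well above background in the NOD channel and between 39.3% and 60.4% in the pool channel. The 12 week pool gave the weakest signal (39.3% to 43.6% of probes), and the weakest NOD signal came from 20 week replicate 5 (42.3%) and replicate 6 (47.6%). Of 18069 genes tested, 13739 (76%) had ratios that differed among the 4 ages by the moderated F test. The median correlation across genes between mice of an age was 0.69 at 10 days, 0.74 at 4 weeks, 0.81 at 12 weeks and 0.69 at 20 weeks, with a lowest pair of 0.19 at 20 weeks. Between ages 11 pairs of arrays were correlated below -0.3, the lowest at -0.54 for 10 day replicate 1 and 20 week replicate 5. Within-array loess sets the median ratio of all genes close to 0. Under median centring in its place, that median was 0.38 at 10 days, -0.15 at 4 weeks, 0.50 at 12 weeks and -0.21 at 20 weeks, and with the scanner's signals it was 0.14, -0.08, 0.25 and -0.16. Median centring subtracted each array's median ratio over all unflagged noncontrol spots, including those of dim probes not tested. Unlike loess, it leaves any trend of the ratio with intensity in place. Directions are therefore relative to the loess-normalized median gene.

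At 10 days, before the islets of NOD mice are infiltrated, genes of the endocrine islet were higher in NOD mice than in their pool and genes of connective tissue were lower, though no list was called at this age with an estimated correlation between genes (lowest adjusted p = 0.58). The hormone genes Ppy (pancreatic polypeptide, 3.19 ± 0.72, SD, n = 6), Pyy (peptide YY, 2.28 ± 0.89), Gcg (glucagon, 2.21 ± 0.65), Sst (somatostatin, 1.91 ± 0.75), Ins2 (1.83 ± 0.86) and Ins1 (insulin, 1.24 ± 0.93) were higher. So were genes of the secretory granule, Scg2 (2.28 ± 0.59), Chga (2.20 ± 0.64) and Resp18 (2.23 ± 0.48). Col1a1, which encodes the main fibrillar collagen, was the lowest named gene (-3.13 ± 1.02), followed by the procollagen peptidase Adamts2 (-2.71 ± 0.74), the lymphatic growth factor Vegfd (-2.65 ± 0.43), the growth gene Mest (-2.53 ± 0.40), the collagen gene Col5a1 (-2.50 ± 0.57) and the growth factor Igf2 (-2.48 ± 0.30).

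Among the 26 beta cell genes measured at 10 days, 14 rose, 0 fell and 12 did not pass the test, with the zinc transporter Slc30a8 (1.83 ± 0.56) and the glucose-6-phosphatase G6pc2 (1.77 ± 0.82) among those higher. Slc2a2 (0.91 ± 0.63), Mafa (0.43 ± 0.34) and Pdx1 (0.29 ± 0.34) did not reach the 2-fold floor by their reported probes. The other probe of Slc2a2 read 1.35. Of 17 genes of the other endocrine cells 7 rose, and of 13 islet autoantigens 7 rose. Of 16 stellate cell and fibroblast genes 11 fell, including Lum (-2.12 ± 0.72) and Col1a2 (-2.08 ± 0.92), and of 6 adipocyte genes 5 fell, including Adipoq (-1.62 ± 0.24). The lists of endothelial genes (2 of 12 fell, Vwf -1.97 ± 0.86), cell cycle genes (2 of 27 fell, Cdc20 -1.48 ± 0.49) and genes immature or disallowed in beta cells (1 of 16 fell, Zdhhc9 -1.09 ± 0.17) were lower by the list test, but not with an estimated correlation (adjusted p = 0.608, 0.581 and 0.58), and their medians turned positive under median centring (0.20, 0.08 and 0.16). Acinar genes did not move as a list (median -0.09, adjusted p = 0.707; adjusted p = 0.952 with an estimated correlation). The enzymes Amy2a5 (1.49 ± 0.82) and Pnlip (1.44 ± 0.95) rose, while the acinar transcription factors Rbpjl (-1.75 ± 0.77) and Bhlha15 (-1.23 ± 0.66) fell. Among genes that respond to tissue handling, the heat shock gene Hspa1a rose (1.80 ± 0.59) and the immediate early genes Egr1 (-1.75 ± 0.53) and Fosb (-1.71 ± 0.66) fell. Of 17 B cell genes 4 fell and of 22 chemokine genes 3 fell, in lists that were not called, and no T cell gene of 23 was called. Lyz2, a macrophage gene, fell with a wide spread (-2.16 ± 2.20).

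At 10 days 718 genes were called, 291 higher (40.5%) and 427 lower, and 683 of them had the same sign in all 6 mice. The higher share was 98.1% of 2754 genes under median centring, 67% of 3071 with the scanner's signals and 54.2% of 2433 in the deposited table. By camera 8 of 28 lists were called: beta cell (adjusted p = 1.33e-06), stellate (3.01e-06), cell cycle (9.97e-07), adipocyte (0.000321), endothelial (0.000528), autoantigens (0.000566), other endocrine (0.00443) and immature (0.00798). The lowest of the 28 was adjusted p = 0.58 with an estimated correlation, so none of these held there.

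At 4 weeks most acinar cell genes (22 of 26) were higher in the NOD islet preparations than in their pool. A minority of beta cell genes (7 of 26) were lower. Both lists were called by camera, but neither with an estimated correlation (adjusted p = 0.963 for both). These ratios do not tell expression within a cell from the share of a cell type, which was not tested at this age. The lipase-related genes Pnliprp1 (2.05 ± 0.24, SD, n = 6) and Pnliprp2 (1.98 ± 0.25), the amylase Amy2a5 (1.82 ± 0.19), the chymotrypsin Ctrc (1.77 ± 0.31) and the carboxypeptidase Cpa1 (1.49 ± 0.20) rose. So did the mitochondrial carrier Slc25a22 (2.01 ± 0.31), the serine synthesis gene Psat1 (1.97 ± 0.33), the keratin Krt20 (1.93 ± 0.61) and Gprc5d (1.89 ± 0.38). Glycam1, a ligand for lymphocyte homing (-3.16 ± 0.81), the opioid precursor Pdyn (-2.67 ± 0.47), the noncoding RNA Malat1 (-1.95 ± 0.19), Meltf (-1.95 ± 0.26) and the syndecan Sdc2 (-1.93 ± 0.16) were lower.

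Of 26 acinar genes at 4 weeks 22 rose, 0 fell and 4 did not pass, and of 26 beta cell genes 7 fell, 0 rose and 19 did not pass. Ins1 (-1.49 ± 0.44), the transcription factors Nkx2-2 (-1.39 ± 0.21) and Nkx6-1 (-1.35 ± 0.17) and the glucose transporter Slc2a2 (-1.11 ± 0.46) fell. For Slc2a2 this was the reported probe, and its other probe read -0.25. Ins2 (-0.72 ± 0.52), Gcg (-0.45 ± 0.52) and Sst (-0.83 ± 0.31) were not called. Of 16 genes immature or disallowed in beta cells 5 rose, among them lactate dehydrogenase Ldha (1.40 ± 0.17) and Gast (1.33 ± 0.26). Deaf1, a transcription regulator, rose by its reported probe (1.53 ± 0.32), while its other probe read -0.14. The adenosine receptor Adora2a also rose (1.55 ± 0.35). The Reg genes Reg3d (1.53 ± 0.72) and Reg1 (1.27 ± 0.45) rose among 6 measured, the duct genes Tff2 and Sox9 rose among 14, and the class II chaperone gene H2-DMb1 fell (-1.35 ± 0.25). The interferon gamma list was called higher with 1 of 23 genes past the test, Gbp2 (1.18 ± 1.74), and the unfolded protein list with 2 of 23, Sel1l (1.52 ± 0.98) and Creld2 (1.13 ± 0.28), but neither with an estimated correlation (adjusted p = 0.963 for both). The interferon gamma mean was above 0 in 3 of the 6 mice and ran from -0.53 to 1.92. Cd6 (1.36 ± 0.40) was the only T cell gene of 23 called. In the erythroid list the globin genes Hba-a2 (1.33 ± 0.62) and Hba-a1 (1.08 ± 0.65) rose.

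At 4 weeks 503 genes were called, 344 higher (68.4%) and 159 lower, 484 with 1 sign in all 6 mice. The higher share was 17.3% of 780 genes under median centring and 53.5% of 2122 with the scanner's signals. The 6 lists called were beta cell (adjusted p = 2.00e-06), acinar (6.26e-06), immature (0.000327), cell cycle (lower, 0.000574), unfolded protein (0.00802) and interferon gamma (0.0245). The lowest was adjusted p = 0.649 with an estimated correlation. The genes of the acinar list varied together among mice of the same age, with an estimated correlation between genes of 0.953. That value was estimated over the arrays of all ages, so it does not describe 4 weeks alone.

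At 12 weeks, the age of established islet infiltration in NOD mice, the lists of T cell, B cell and antigen presentation genes were higher and those of duct cell and unfolded protein response genes lower by the list test. None was called with an estimated correlation (lowest adjusted p = 0.181), and the medians of the 2 lower lists were above 0 under median centring (0.13 and 0.51). Ccl19, a chemokine that draws T cells and dendritic cells into lymphoid tissue, was the highest (3.95 ± 0.30, SD, n = 6), followed by Wdfy4 (3.17 ± 0.47), which serves cross-presentation, the class II gene H2-Ab1 (2.96 ± 0.20), the integrin Itgb7 (2.94 ± 0.50), S100a4 (2.90 ± 0.53) and the T cell surface protein Cd5 (2.90 ± 0.45). The cytokine Il6 was the lowest (-4.17 ± 0.58), followed by the antimicrobial lectin Reg3g (-3.90 ± 0.43), Fhl2 (-3.12 ± 0.31), the lectin Reg3b (-3.04 ± 0.90), the defensin Defb1 (-2.76 ± 0.48) and the lipid carrier Fabp2 (-2.75 ± 0.68).

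Of 23 T cell genes at 12 weeks 9 rose and 0 fell, including Cd6 (2.69 ± 0.35), Cd3d (2.58 ± 0.60) and Lck (2.45 ± 0.60), while Cd3e (0.18 ± 0.13) was not called. Of 17 B cell genes 8 rose, including Ighm (2.67 ± 0.59) and Pou2af1 (2.39 ± 0.67), and of 15 NK cell and cytotoxic genes 7 rose, including Nkg7 (2.57 ± 0.52) and Ifng (2.43 ± 0.61). Klrd1 was below background in the pool on every array, so its rise is a bound, at least 3.00-fold. Of 22 macrophage and dendritic cell genes 10 rose, among them Aif1 (2.11 ± 0.23), and Cd14 fell (-1.87 ± 0.33). Of 20 MHC and antigen presentation genes 10 rose and 0 fell, and of 27 cell cycle genes 9 rose, including Mcm3 (1.94 ± 0.41). Of 23 interferon gamma genes 10 rose and 2 fell, with Psmb8 (2.62 ± 0.40) and Cxcl9 (2.54 ± 0.41) higher and Cxcl10 lower (-1.35 ± 0.73). The 25 type I interferon genes split, with 3 higher and 6 lower, among them Rsad2 (-2.05 ± 0.65) and Ifit1 (-1.51 ± 0.45), and the list was not called (median -0.20, but 0.56 under median centring). Of the chemokines, Ccl8 (2.53 ± 0.66) rose and Ccl2 (-2.25 ± 0.52) and Ccl7 (-2.07 ± 0.46) fell.

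A minority of the genes of 3 lists fell at 12 weeks. Of 14 duct genes 4 fell, including Krt8 (-2.12 ± 0.50) and Krt19 (-1.98 ± 0.21), and of 23 unfolded protein response genes 7 fell, including Ddit3 (-2.59 ± 0.55) and Trib3 (-2.19 ± 0.22), but under median centring the medians of these lists were 0.13 and 0.51, above 0. The metallothioneins Mt1 (-2.27 ± 0.69) and Mt2 (-2.17 ± 0.67) were among 3 of 18 oxidative stress genes that fell, a list whose median was likewise above 0 under median centring (0.52). The heat shock genes Hspa1a (1.501 ± 0.469) and Hspa1b (1.44 ± 0.36) rose. Of 6 Reg genes 3 fell. Of 26 beta cell genes 6 fell and 1 rose, with a list median of -0.53 that was 0.22 under median centring; Ins2 fell (-1.25 ± 0.39), and Ins1 fell (-1.05 ± 0.33) but was 0.16 under median centring. The adipokine Cfd, below background in the NOD channel, was at least 3.84-fold lower. Col1a2 (1.45 ± 0.38) and Pdgfrb (1.42 ± 0.28) rose among 16 stellate genes.

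At 12 weeks 635 genes were called, 378 higher (59.5%) and 257 lower, 629 with 1 sign in all 6 mice. The higher share was 99.3% of 4289 genes under median centring and 78.8% of 3650 with the scanner's signals. The 15 lists called included cell cycle (adjusted p = 2.49e-13), MHC (1.49e-09), T cell (1.80e-09), unfolded protein (4.98e-07), macrophage (8.37e-07), NK cell (5.47e-06), B cell (7.76e-06), beta cell (1.09e-05) and duct (2.38e-05). Oxidative stress (0.00307), lymphoid tissue (0.00392), stellate (0.0038), interferon gamma (0.00252), Reg (0.00973) and adipocyte (0.0158) completed them. The lowest was adjusted p = 0.181 with an estimated correlation.

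At 20 weeks, when many female NOD mice are diabetic, immune genes were the highest and 17 of 26 beta cell genes fell, though no list was called with an estimated correlation (lowest adjusted p = 0.166). The T cell costimulator Icos (3.88 ± 0.57, SD, n = 6), the chemokines Ccl19 (3.87 ± 0.55), Ccl8 (3.80 ± 0.67) and Cxcl9 (3.72 ± 0.56), the ubiquitin-like gene Ubd (3.62 ± 0.45) and Ms4a4b (3.58 ± 0.87) led. The lectin Cd209b (-2.95 ± 0.53), Fabp2 (-2.84 ± 1.05), Reg3a (-2.72 ± 1.57), the defensin Defa24 (-2.52 ± 0.69), Reg3b (-2.49 ± 1.23) and the neuropeptide Npy (-2.22 ± 0.69) were among the lowest.

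Of 23 T cell genes at 20 weeks 16 rose and 0 fell, including Cd3d (3.36 ± 0.64) and Cd8a (2.15 ± 0.50), while Cd3e (0.40 ± 0.33) and Cd4 (0.23 ± 0.06) were not called. Of 22 macrophage and dendritic cell genes 16 rose, including Clec7a (3.04 ± 0.62), of 17 B cell genes 11, including Ighm (2.41 ± 1.08), of 15 NK cell and cytotoxic genes 8, including Ifng (2.85 ± 1.04), and of 8 plasma cell genes 3. Of 23 interferon gamma genes 20 rose, of 20 MHC genes 13, including H2-Aa (3.09 ± 0.36) and B2m (2.90 ± 0.65), and of 22 chemokine genes 12. Of 25 type I interferon genes 9 rose, including Zbp1 (2.64 ± 0.55), and Ifit1 (0.32 ± 1.75) was not called. Glycam1 (3.01 ± 1.35) and Vcam1 (2.98 ± 0.73) were among 10 of 21 lymphoid tissue genes that rose, and Birc5 (2.18 ± 0.43) was among 8 of 27 cell cycle genes. The beta cell list had 17 of 26 genes lower and 0 higher: Ins1 (-1.72 ± 1.73) and Slc2a2 (-1.62 ± 1.43) fell with a wide spread (-1.04 and -1.075 without replicate 5, the dimmest NOD sample), and Mafa (-1.12 ± 0.25) and Pdx1 (-1.03 ± 0.33) fell more evenly. Gcg (-0.88 ± 1.12), Sst (-0.45 ± 1.07) and Ppy (-0.51 ± 1.43) were not called, and were -0.49, -0.0353 and 0.0585 without replicate 5. Of 13 autoantigens 6 fell, and of 16 stellate genes 4 rose, such as Dcn (1.53 ± 0.66). Ldha (2.05 ± 0.16) and Slc16a1 (1.53 ± 0.19), which are normally silent in beta cells, rose. The RNA came from whole islets, so the rises of Ldha and Slc16a1 are not placed in a cell type.

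At 20 weeks 922 genes were called, 700 higher (75.9%) and 222 lower, 886 with 1 sign in all 6 mice. The higher share was 24.8% of 1823 genes under median centring, 46.6% of 3066 with the scanner's signals and 48.4% of 2343 in the deposited table. Without the 2 dimmest NOD samples, a choice made after the data were seen, 1043 genes were called, 90.2% of them higher. Fewer genes were thus called lower than with all samples. Of the 15 lists called, the lowest adjusted p values were those of the T cell (1.05e-13), cell cycle (2.86e-13), macrophage (1.39e-11), interferon gamma (5.05e-11), NK cell (5.05e-11), MHC (8.98e-11), beta cell (3.31e-10) and B cell (2.02e-08) lists, and the lowest of all was adjusted p = 0.166 with an estimated correlation.

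**Figure D1:**
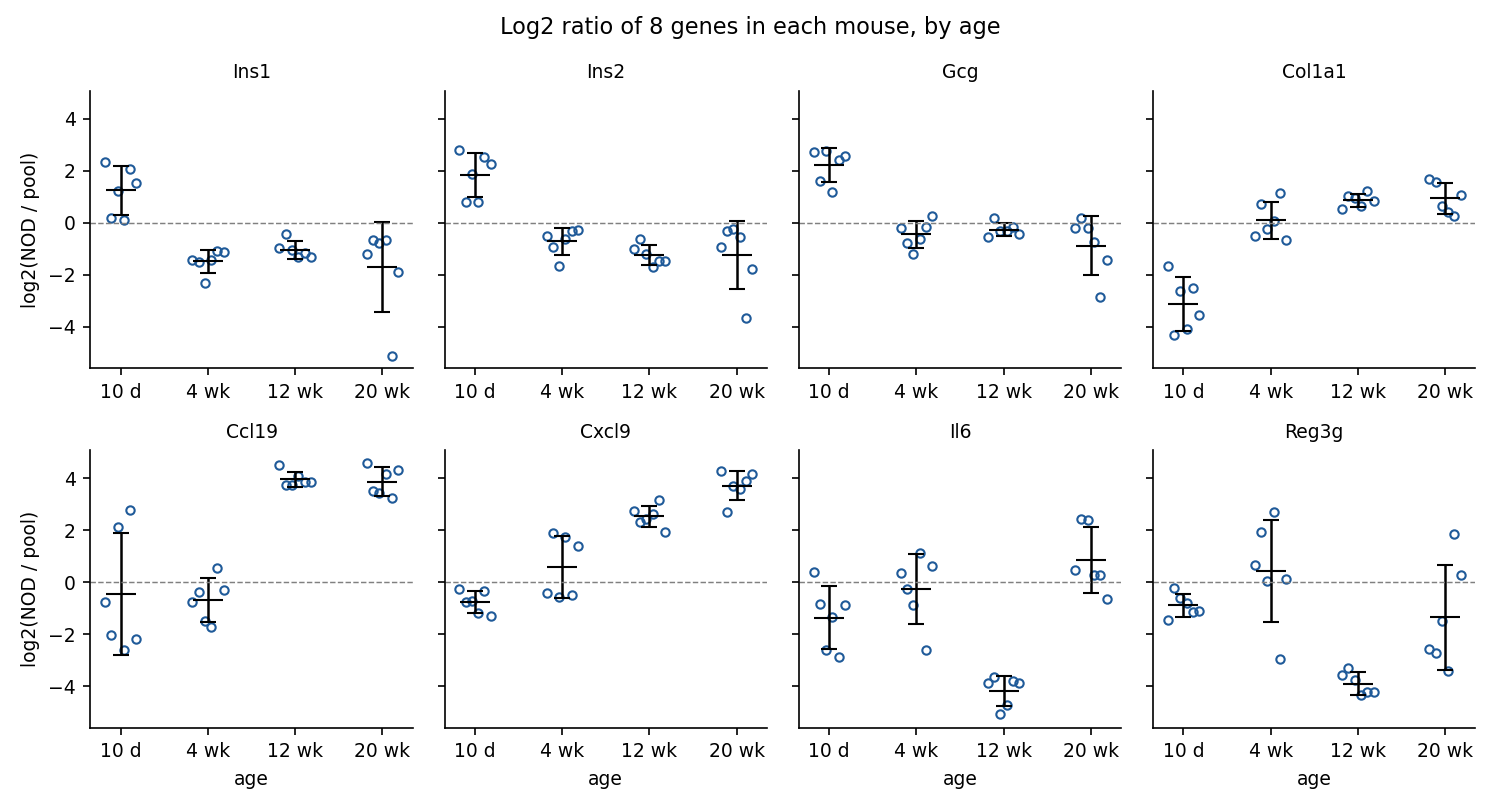
Log2(NOD/pool) of 8 genes in each mouse by age; each point is 1 mouse (6 per age), bars are the mean and its SD. Ins1 was above 0 in the mean at 10 days (1.24) and below 0 at 4, 12 and 20 weeks (-1.49, -1.05 and -1.72, the 12 week value being 0.16 under median centring), and 20 week replicate 5 lies at -5.11.

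The contrast of 4 weeks against 10 days asked how the islet ratio moved in early life. Endocrine genes fell relative to the pools and connective tissue and acinar genes rose, in lists not called with an estimated correlation. Ppy (log2 difference -4.07 ± 0.62, SE), Chga (-2.93 ± 0.33), Ins1 (-2.73 ± 0.55), Gcg (-2.67 ± 0.39), Glycam1 (-3.88 ± 0.72) and Hspa1a (-2.86 ± 0.31) fell. Celsr1, a cell polarity gene (3.26 ± 0.49), Col1a1 (3.21 ± 0.38), Ptger3 (3.04 ± 0.50), the glypican Gpc3 (3.02 ± 0.26) and the hexokinase-like Hkdc1 (2.92 ± 0.40) rose. Of 26 beta cell genes 24 fell, of 17 other endocrine genes 9 fell and of 13 autoantigens 9 fell. Of 26 acinar genes 19 rose (20 when adjusted over the list alone), of 16 stellate genes 10, of 6 adipocyte genes 5, of 16 immature or disallowed genes 8 and of 23 interferon gamma genes 5. In all 1627 genes were called, 932 higher (57.3%) and 695 lower; the higher share was 1.9% of 5903 under median centring, whose all-gene median was -0.60, and 36.6% of 4686 with the scanner's signals. All these lists passed camera, the beta cell list with adjusted p = 1.10e-11, and the lowest of the lists was adjusted p = 0.143 with an estimated correlation. On the slide that held 2 arrays of each age the beta cell list differed by -2.15 against -1.78 in the whole data, and the acinar list by 1.74 against 1.53; of 1475 genes at least 2-fold apart on the other slides, 1473 (99.9%) had the same sign on this slide.

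Between 4 and 12 weeks most MHC genes and part of the T cell, B cell and macrophage genes rose, while most acinar and part of the duct cell genes fell, in lists not called with an estimated correlation. Immune genes also fell, such as Il6 and Ccl2. A fall here includes any rise of the pool from 4 to 12 weeks. Glycam1 (4.69 ± 0.72, SE), Ccl19 (4.64 ± 0.70), Ccdc88b (3.51 ± 0.41), complement C3 (3.34 ± 0.61) and Wdfy4 (3.24 ± 0.54) were among those that rose most. Reg3g (-4.32 ± 0.78), Il6 (-3.90 ± 0.62), Reg3b (-3.25 ± 0.90), Mt2 (-3.17 ± 0.51), Mt1 (-3.06 ± 0.44), Ccl2 (-2.88 ± 0.62), Tnfrsf12a (-2.75 ± 0.48) and Krt8 (-2.69 ± 0.52) were among those that fell most; mice of the 2 ages overlapped in Reg3b and Ccl2. Of 20 MHC genes 15 rose, among them Cd74 (2.99 ± 0.44), of 27 cell cycle genes 14, of 23 T cell genes 9, of 22 macrophage genes 9 with 1 lower, and of 17 B cell genes 6. Of 26 acinar genes 17 fell (20 when adjusted over the list alone), of 14 duct genes 6, and of 6 Reg genes 4 (5 over the list alone). Of 23 unfolded protein genes 10 fell, with a list median of -0.79 that was 0.54 under median centring, while the heat shock genes Hspa1a (2.56 ± 0.31) and Hspa1b (2.41 ± 0.25) rose. The globins Hba-a2 (-1.89 ± 0.33) and Hba-a1 (-1.86 ± 0.33) fell in a list of 4. Of 26 beta cell genes 2 rose and 0 fell. In all 1094 genes were called, 538 higher (49.2%) and 556 lower; the higher share was 99.6% of 7102 under median centring (all-gene median 0.73) and 74% of 4747 with the scanner's signals. Of 13 lists called, cell cycle had adjusted p = 2.01e-15, unfolded protein 8.14e-10 and MHC 1.71e-08, and the lowest was adjusted p = 0.175 with an estimated correlation. No slide held arrays of both ages, so slide and age cannot be told apart in this contrast.

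From 12 to 20 weeks 11 of 22 chemokine genes and Il6 rose, the list not being called with an estimated correlation. A rise here includes any fall of the pool from 12 to 20 weeks. In the 257 genes called lower at 12 weeks, that pool was higher than at 4 and 20 weeks by a median of 0.76 and the NOD mice lower (-0.51). The pool and the NOD mice cannot be told apart as the source there. Il6 (5.03 ± 0.62, SE), Ccl2 (3.70 ± 0.62) and Ccl7 (3.65 ± 0.49), which draw monocytes, Cxcl10 (3.20 ± 0.68), Cxcl1 (3.13 ± 0.47) and P2ry10 (2.85 ± 0.31) were among those that rose most, and Il6 and Ccl2 had been among the genes below the pool at 12 weeks. The heat shock genes Hspa1b (-1.88 ± 0.25) and Hspa1a (-1.72 ± 0.31), Malat1 (-1.64 ± 0.45, with overlap between the mice of the 2 ages), the endocrine crystallin Cryba2 (-1.52 ± 0.26) and Rec8 (-1.45 ± 0.17) were among the called genes that fell most. Of 22 chemokine genes 11 rose (median 1.02), of 23 interferon gamma genes 11 (1.17) and of 23 T cell genes 3 (0.50), but these medians were -0.02, -0.27 and -0.18 under median centring, where the median of all genes was -0.78. Of 25 type I interferon genes 8 rose (9 over the list alone), such as Rsad2 (2.59 ± 0.96). Of 26 beta cell genes 3 fell, such as Slc30a8 (-1.23 ± 0.32), while Ins1 (-0.67 ± 0.55) was not called. Cxcl9 rose (1.18 ± 0.39) but was -0.42 under median centring. In all 435 genes were called, 363 higher (83.4%) and 72 lower. Of the 435, 171 stayed called with slide as a fixed block, which rests on 2 arrays against 2. The higher share was 0.3% of 7663 under median centring, 17.1% of 3409 with the scanner's signals, 39.2% of 1985 in the deposited table and 64.1% of 1075 with a normexp offset of 0. Of 17 lists called, chemokines had adjusted p = 2.27e-08 and the lowest was adjusted p = 0.181 with an estimated correlation. On the slide shared by 2 arrays of each age the T cell list differed by 0.94 (0.58 in the whole data), the beta cell list by -0.13 (-0.56) and the acinar list by -1.88 (0.01), and of 614 genes at least 2-fold apart on the other slides, 513 (83.6%) had the same sign there.

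Over the whole span, 20 weeks against 10 days, the ratio of beta cell genes fell and those of immune, cell cycle and connective tissue genes rose, in lists not called with an estimated correlation. Icos (4.74 ± 0.34, SE), Cxcl9 (4.48 ± 0.39), Ccl19 (4.33 ± 0.70), the apolipoprotein Apol6 (4.27 ± 0.21), the lysozyme Lyz2 (4.09 ± 0.71) and Col1a1 (4.06 ± 0.38) were among those that rose most. Ppy (-3.70 ± 0.62), the co-chaperone Dnaja4 (-3.54 ± 0.38), Pcsk1n (-3.34 ± 0.39), Esm1 (-3.29 ± 0.32), Galnt14 (-3.29 ± 0.43) and Chga (-3.23 ± 0.33) were among those that fell most, and Ins2 (-3.08 ± 0.46) and Ins1 (-2.96 ± 0.55) fell. Of 26 beta cell genes 25 fell and of 17 other endocrine genes 9 fell. Of 23 interferon gamma genes 22 rose, of 27 cell cycle genes 17, of 22 macrophage genes 16, of 23 T cell genes 16, of 16 stellate genes 12, of 17 B cell genes 12 and of 16 immature or disallowed genes 11. In all 2266 genes were called, 1399 higher (61.7%) and 867 lower; the higher share was 6.3% of 7067 under median centring (all-gene median -0.64), 36.3% of 6038 with the scanner's signals and 45% of 4677 in the deposited table. Camera called 17 lists, with cell cycle at adjusted p = 1.51e-14 and beta cell at 4.33e-12; the lowest was adjusted p = 0.191 with an estimated correlation. No list in any of the 8 comparisons was called by camera of limma with an estimated correlation (1, 1, 4 and 6 lists at the 4 ages and 3, 3, 2 and 4 in the contrasts at unadjusted p < 0.05), while fry, which asks whether a list moves on balance without comparing it with other genes, called 13, 12, 19 and 20 lists at the 4 ages and 10, 15, 15 and 19 in the contrasts as ordered here. Slides held 1 of these ages only, so slide and age cannot be told apart here either.

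Counts adjusted over the list alone equalled those over all genes except where given above and in these cases. At 10 days they were 3 for B cell genes (4 over all genes) and 2 for chemokine genes (3), and at 12 weeks 0 for acinar genes (1) and 1 for autoantigens (2). For 4 weeks against 10 days they were 1 for chemokine genes (2), and for 12 against 4 weeks 7 for NK cell genes (6). For 20 against 12 weeks they were 4 for duct genes (3), 12 for interferon gamma genes (11) and 0 for stellate genes (1). For 20 weeks against 10 days they were 4 for type I interferon genes (6) and 0 for acinar genes (1). Median, mean and test differed in sign only in lists that were not called. These were the NK cell, interferon gamma and oxidative stress lists at 10 days; the T cell, B cell, macrophage, chemokine and oxidative stress lists at 4 weeks; the other endocrine and endothelial lists at 12 weeks; and the acinar and adenosine lists at 20 weeks. In the contrasts they were the T cell, NK cell, MHC, oxidative stress and immediate early lists from 10 days to 4 weeks, the adenosine list from 4 to 12 weeks, and the immediate early and adenosine lists from 12 to 20 weeks. Among called genes with several probes, a probe of opposite sign was found for 23 of 263 genes at 10 days, 19 of 162 at 4 weeks, 15 of 212 at 12 weeks and 6 of 311 at 20 weeks. In the contrasts as ordered above it was found for 48 of 578, 40 of 359, 10 of 172 and 52 of 840 genes, and the probe of opposite sign was itself called for 1 gene from 10 days to 4 weeks and 2 from 4 to 12 weeks.

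The mean of each list per mouse gave the same contrast as a single value. The mice of an age were read as sharing a pool, and these ages shared no slide. An offset of a pool or of a slide could therefore also give a low p in the permutation test. The beta cell mean was 0.97 at 10 days and -1.12 at 20 weeks (n = 6 each; difference -2.09, exact permutation p = 0.00217, the smallest the test can give, adjusted p = 0.00379). The same exact p and adjusted p were found for 15 further lists: other endocrine (difference -1.26), autoantigens (-1.90), T cell (1.70), B cell (1.65), plasma cell (0.82), macrophage and dendritic cell (1.65), NK cell (1.51), lymphoid tissue (1.56), interferon gamma (2.07), MHC (1.69), chemokines (1.57), immature or disallowed (1.09), cell cycle (1.39), stellate (2.07) and adipocyte (1.35). By the same exact test, adjusted p was 0.00713 for Schwann cell genes (0.56), 0.0202 for neutrophil genes (1.08), 0.0351 for endothelial genes (0.56) and 0.0455 for erythroid genes (-0.62). Under median centring the Schwann and endothelial differences were -0.07 and -0.59, and those of the immature (0.09), plasma cell (0.29), cell cycle (0.49), MHC (0.76), macrophage (0.82), chemokine (0.82), lymphoid tissue (0.96), stellate (0.98) and interferon gamma lists (1.10) were smaller by over 1.5 times. Those of the beta cell (-3.22), other endocrine (-2.35), autoantigen (-2.98) and erythroid lists (-1.41) were larger by over 1.5 times. The other 8 lists did not pass: acinar (0.11, exact adjusted p = 0.868), Reg (-0.19), duct (-0.15), type I interferon (0.71, exact adjusted p = 0.124), unfolded protein (-0.09), oxidative stress (0.02), immediate early (0.34) and adenosine signalling (-0.10).

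**Figure D2:**
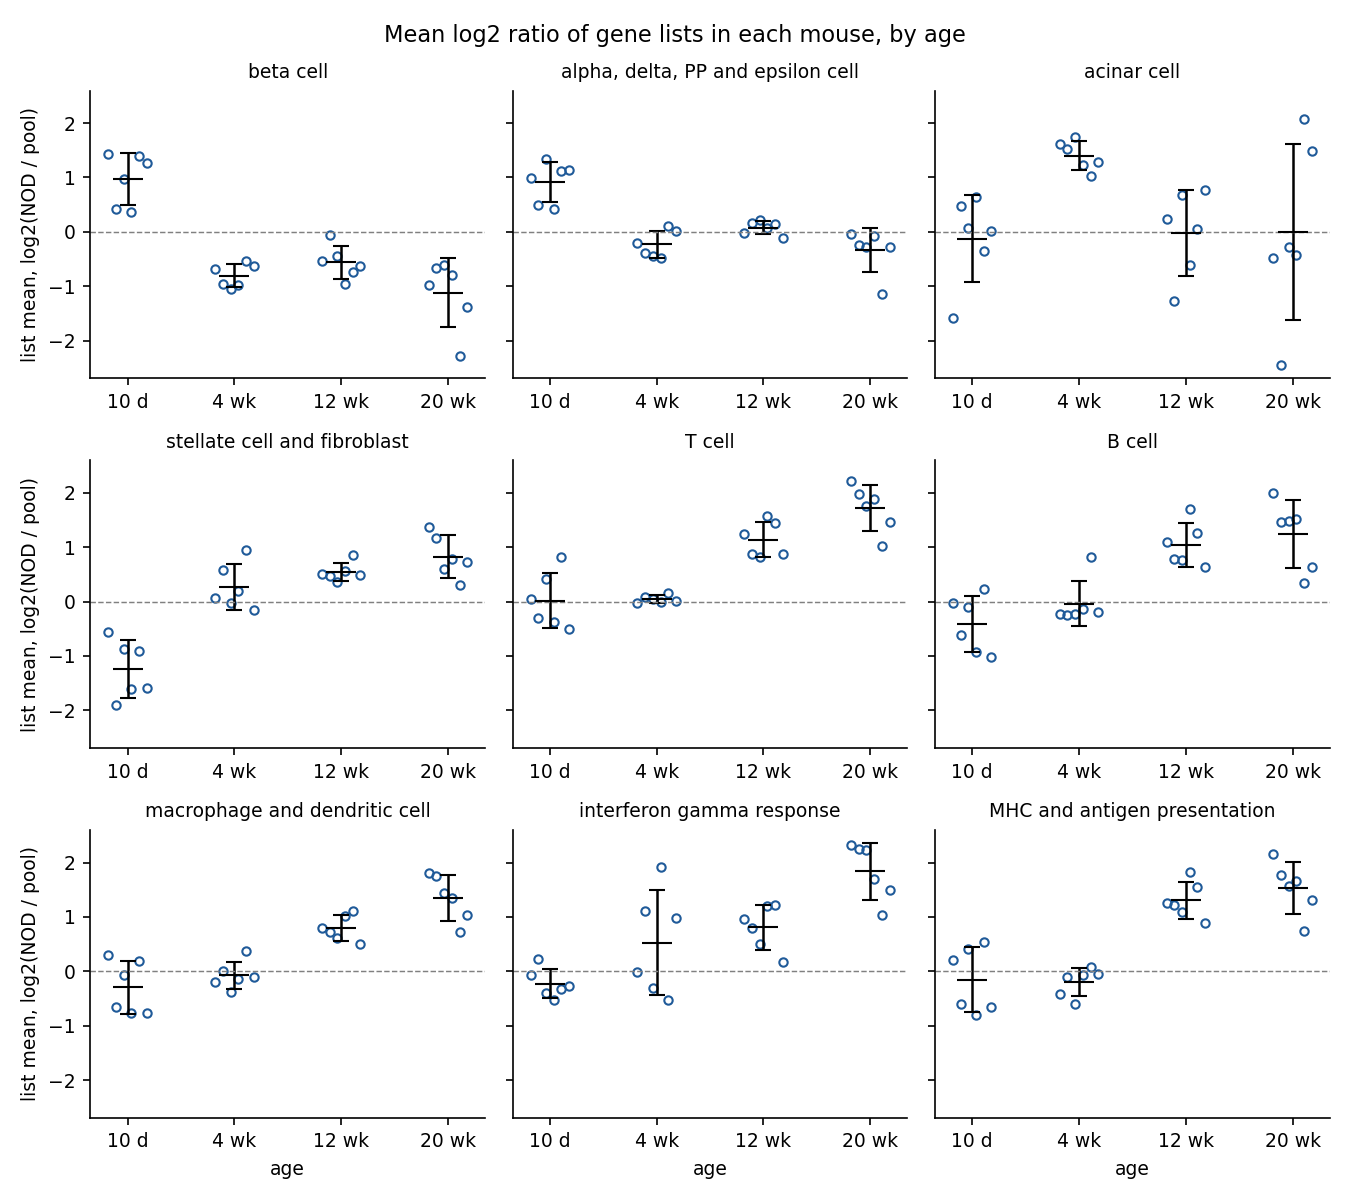
Mean log2(NOD/pool) of 9 gene lists in each mouse by age; each point is 1 mouse (6 per age), bars are the mean and its SD. The T cell mean lies near 0 at 10 days (0.02) and 4 weeks (0.04) and at 1.14 and 1.72 at 12 and 20 weeks, while the acinar mean spreads most among the 20 week mice.

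Genes called at 1 age were compared with those called at another, each age having its own pool. The 12 and 20 week sets shared 316 higher genes (14.6 expected if independent) and 42 lower genes (3.2 expected). The 4 and 20 week sets shared 69 lower genes (2 expected). All arrays had the same dye orientation, so a dye effect on a probe could add to the genes shared in one direction. Of the genes higher at 10 days, 84 were lower at 20 weeks (3.6 expected), and 68 went from lower to higher (16.5 expected). Across genes, which are not independent replicates, the mean ratios correlated at 0.64 between 12 and 20 weeks and at -0.21 between 10 days and 20 weeks.

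A set of 39 genes was at least 1.5-fold off in the same direction at every age, 27 higher and 12 lower, and 3 of them at least 2-fold (D17H6S56E-5, Sdc2 and Zfp871). Chromosome 17, which carries the MHC that the strains' labels name as their difference, held 9 of the 39 (23.1%, against 4.89% of tested genes; odds ratio 5.88, two-sided Fisher's exact p = 8.69e-05, adjusted over chromosomes 0.00174). These were chosen after their values were seen. Zfp871 (probe at 32910629 to 32910688 of chromosome 17, mm9) read -1.29, -1.58, -1.23 and -1.62 at the 4 ages in order. D17H6S56E-5 (35134128 to 35134187) read -2.01, -2.11, -1.14 and -1.30. Psmb8, an immunoproteasome gene within the MHC (34337771 to 34337830), read 0.68, 0.84, 2.62 and 2.24. Glo1 (30729951 to 30730010) read 1.07, 1.09, 0.99 and 0.78. The other members were Tcp1, BC034637, Zfand3, Sik1 and Gm6548. A second probe of D17H6S56E-5 read -2.05, -2.24, -1.10 and -1.52, and the second probe of Psmb8 was above 0 at each age. The second probe of Glo1 read -0.53, -0.35, -0.42 and -0.45, opposite in sign at every age, and the 2 other probes of Zfp871 read between -0.19 and 0.21.

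**Figure D3:**
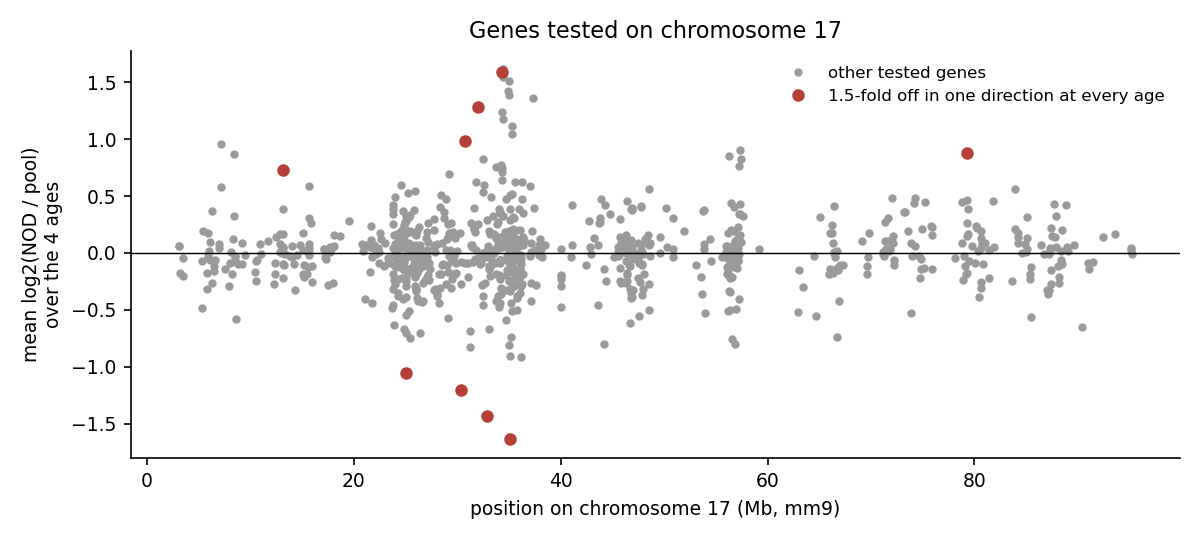
Mean log2(NOD/pool) over the 4 ages of each tested gene on chromosome 17 against its position (Mb, mm9); red points are the 9 genes at least 1.5-fold off in one direction at every age. Of these, 8 lie from the probe of Tcp1 to that of D17H6S56E-5, and Gm6548 lies further along the chromosome.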

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

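The tests of the islet share and of dye bias below were chosen after the results they concern were seen, and the others before. Of 273 groups of 6 mice, 19 had a mouse far from the others by Dixon's criterion, where chance marks about 1 in 20 groups (13.7 expected), and 8 of the 19 were list means. In 20 week replicate 5 these were Ins1 (-5.11), Slc2a2 (-4.32), Ppy (-3.33), Sst (-2.55) and the mean of the alpha, delta, PP and epsilon cell list (-1.14). In 4 week replicate 5 they were Cxcl13 (2.28), Ms4a1 (1.72), Glycam1 (-1.60) and the B cell (0.81), neutrophil (1.15) and adenosine signalling (0.0113) list means. Further single mice were 10 day replicate 1 for the neutrophil mean (1.15), 10 day replicate 2 for the type I interferon mean (0.95), 20 week replicate 2 for the neutrophil mean (1.57) and 20 week replicate 4 for the adipocyte mean (1.13). The remaining genes were Ins1 (-2.31) and Cd4 (0.62) in 4 week replicate 3, Wdfy4 in 12 week replicate 4 (4.10) and Cd3e in 12 week replicate 2 (-0.0863). No explanation for these single mice was tested.

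The difference of list means between 20 weeks and 10 days passed its exact permutation test in 20 lists. That test does not exclude an offset of a pool or of a slide. The differences were -2.09 for beta cell, -1.26 for other endocrine, -1.90 for autoantigen and -0.62 for erythroid genes. They were 1.70 for T cell, 1.65 for B cell, 0.82 for plasma cell, 1.65 for macrophage and dendritic cell, 1.51 for NK cell, 1.08 for neutrophil and 1.56 for lymphoid tissue genes. They were 2.07 for interferon gamma, 1.69 for MHC, 1.57 for chemokine, 1.09 for immature or disallowed and 1.39 for cell cycle genes, and 0.56 for endothelial, 2.07 for stellate, 0.56 for Schwann cell and 1.35 for adipocyte genes.

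Counts of genes that differ between ages were set against 100 splits of the same arrays. In each case only 1 split, the real one, reached the real count, so a random grouping of the arrays can be excluded for these counts. The arrays of an age were read as sharing a pool, which a split of arrays does not draw anew. An offset of a pool or of a slide is therefore not excluded by these splits. The counts were 1627 from 10 days to 4 weeks (highest other split 542), 1094 from 4 to 12 weeks (561), 435 from 12 to 20 weeks (346), 2266 from 10 days to 20 weeks (1142) and 13739 over the 4 ages (2672). The 17 lists called for 20 weeks against 10 days were reached by 36 of 100 splits, the highest of the others with 21 lists, so chance cannot be excluded for the number of lists. That test takes genes of a list as nearly independent, and their estimated correlation ran up to 0.953.

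Endocrine genes were higher and fibroblast genes lower at 10 days. Weak signal was argued against, since the beta cell list over probes above background in both channels on all arrays had a median of 1.22 over 20 genes, 114.3% of that over all. A larger islet share in the NOD mice than in their pool may account for both directions, and its test left it open: the acinar mean minus the stellate mean was 1.12 with an SD of 1.27, above 0 in 5 of 6 mice. The duct mean was -0.07 (SD 0.47) and the stellate mean -1.24 (SD 0.53), so these 2 lists did not fall alike. Whether a larger islet share would lower all other cell types alike was not tested. The share therefore stays open, for part of the pattern or the whole. A difference between the strains at this age, which the design names, also stays open and was not tested.

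The 257 genes called lower at 12 weeks stood against the pool with the weakest signal. Weak signal in that pool stays open: 100% of these genes were above background in it on all 6 arrays, but so were 100% of 631 uncalled genes at least 1.5-fold below the pool, so the choice of genes fixed that outcome. A high level in the 12 week pool may contribute: the pool was higher than at 4 and 20 weeks by a median of 0.76 and the NOD mice lower by a median difference of -0.51, so the pool made up 59.9% of the sum, on levels normalized between arrays. In the 378 genes called higher the pool was also higher, by a median of 0.81 (NOD mice 1.30), so a higher pool level was not particular to the genes called lower. Over all 18069 genes tested the medians were -0.03 for the pool and -0.02 for the NOD mice. The normalization between arrays holds these medians close to 0. The share of 59.9% lay between the bounds set beforehand for and against, so the pool and the NOD mice cannot be told apart as the source.

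Genes 1.5-fold off at every age gathered on chromosome 17. A dye effect of single probes has no reason to follow a chromosome, so the gathering as a whole argues against it (Fisher's exact p = 8.69e-05, odds ratio 5.88). That p is the value by which the gathering was seen, and it excludes nothing for single genes: the second probe of Glo1 had the opposite sign at every age and the 2 other probes of Zfp871 lay near 0. For the other chromosomes a dye effect stays open (smallest exact p = 0.0182). Sequence differences between the strains under single probes stay open, since 40% of the other probes (2 of 5, fewer than the 6 the test needed) kept the sign at all 4 ages. Linkage to the H2 haplotype by which the strains differ is a candidate explanation that the labels name and that was not tested further.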

How the results depend on the processing

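All alternatives below were planned, except leaving out the 2 dimmest NOD samples, which was chosen after the data were seen. Counts are given for 10 days, 4, 12 and 20 weeks, then for 4 weeks against 10 days, 12 against 4, 20 against 12, and 20 weeks against 10 days. Leaving out each array in turn gave 648 to 805, 410 to 597, 557 to 706, 859 to 1001, 1532 to 1744, 966 to 1279, 364 to 482 and 2155 to 2364 genes, 13149 to 14220 in the F test, and 8 to 8, 5 to 9, 15 to 16, 15 to 16 and 16 to 18 lists, all within 1.5 times the reported counts. Counts of genes also stayed within that range with no background correction, outlier spots kept, no filter on dim probes, the median of a gene's probes, robust or weighted spread estimates, the compared ages alone, slide as a random or fixed block, and without the 2 dimmest samples. These are total counts. Without the 2 dimmest samples fewer genes were called lower at 20 weeks, and more higher. Signal over background limits the 12 week pool most, with a median of 8.5 to 11.6 times, and 20 week replicate 5, with 7.6 times.

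With median centring in place of loess the counts were 2754, 780, 4289, 1823, 5903, 7102, 7663 and 7067. Median centring leaves any trend of the ratio with intensity in place, which loess removes. How far such a trend accounts for these counts was not tested. Genes called in at least 1 of the 2 fits that turned sign under it were Spink1 (0.14), Ins1 (0.16), Fosb (0.0742) and Dnajb1 (0.15) at 12 weeks, Krt19 (-0.0833) and Adora1 (-1.01) for 4 weeks against 10 days, Atf3 (0.29) and Adora2a (0.10) for 12 against 4 weeks, and Sox9 (-0.00462) and Edem1 (-0.37) for 20 weeks against 10 days. For 20 against 12 weeks they were Krt8 (-0.0269), Krt18 (-0.35), Krt19 (-0.21), Gbp3 (-0.21), Irgm1 (-0.23), Herpud1 (-0.22), Txnrd1 (-0.72), Ldha (-0.66), Dcn (-0.70), Cxcl9 (-0.42), Deaf1 (-1.56) and Cpa1 (-1.55), of which Deaf1 and Cpa1 were called under median centring alone, as was Adora1 for 4 weeks against 10 days. List means for 20 weeks minus 10 days turned sign for endothelial (-0.59) and Schwann cell genes (-0.067), which had passed their test, and for type I interferon (-0.0108), acinar, oxidative stress and immediate early genes, which had not. They moved by more than their spread for beta cell -3.22, other endocrine -2.35, acinar cell -1.26, Reg family -1.52, duct cell -1.22, plasma cell 0.29, macrophage 0.82, lymphoid tissue 0.96, interferon gamma 1.10, MHC 0.76, chemokines 0.82, unfolded protein -1.44, oxidative stress -1.14, immature 0.0903, islet autoantigens -2.98, cell cycle 0.49, stellate 0.98, erythroid cell -1.41, immediate early -1.05 and adenosine signalling -1.04.

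With the scanner's processed signals the counts were 3071, 2122, 3650, 3066, 4686, 4747, 3409 and 6038, and list means moved to beta cell -2.97, other endocrine -1.76, T cell 3.14, B cell 2.70, plasma cell 1.59, NK cell 3.37, neutrophil 1.77, lymphoid tissue 2.53, chemokines 2.24, oxidative stress -0.17, islet autoantigens -2.67, cell cycle 2.11, Schwann cell 0.88, adipocyte 3.11 and adenosine signalling -0.34. In the deposited table, with 15714 genes, the counts were 2433, 1550, 2645, 2343, 3758, 3535, 1985 and 4677, and list means moved to beta cell -2.89, T cell 3.22, B cell 2.87, plasma cell 1.61, macrophage 2.24, NK cell 3.98, lymphoid tissue 2.80, interferon gamma 2.48, chemokines 2.44, oxidative stress -0.18, immature 1.32, islet autoantigens -2.62, cell cycle 2.19, Schwann cell 1.02 and adenosine signalling -0.41. Acinar means turned sign in both (-0.23 and -0.0773), without a call. The cause was not tested. A normexp offset of 0, which leaves dim ratios unshrunk, gave 1693, 1008, 1503, 1793, 3076, 2447, 1075 and 4183. Loess followed by scaling gave 1066 genes at 12 weeks; the cause was not tested. Keeping only probes above background in both channels on all arrays left fewer genes to test and 8881 in the F test.

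Without a fold floor the counts were 9232, 9235, 6773, 8846, 9203, 7502, 4835 and 9730, and with a floor of 1.5-fold 2618, 2144, 1864, 2594, 3941, 2898, 1634 and 4820. A test against a 1.5-fold change called 143 genes at 4 weeks, 1031 for 4 weeks against 10 days, 288 for 12 against 4 weeks and 46 for 20 against 12 weeks. These follow from the thresholds. With an estimated correlation between genes, camera of limma called 0 lists at each of the 4 ages and 0 for 20 weeks against 10 days (1, 1, 4, 6 and 4 at unadjusted p < 0.05). Fry called 13 lists at 10 days and 12 at 4 weeks, and with slide as a random block 14 and 13.

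Replicate numbers do not pair the mice: arrays with the same number at different ages correlated at a mean of -0.032 over 36 pairs, against 0.006 over 180 other pairs, and 5 of 24 arrays had their best match among arrays of their own number. With replicate number as a replicate block the counts were 716, 502, 632, 921, 1626, 1087, 425 and 2266, with 13202 in the F test.

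With slide as a fixed block, which rests on 2 arrays against 2, 1871 genes were called for 4 weeks against 10 days (1387 of the reported 1627) and 334 for 20 against 12 weeks (171 of 435). Of 11591 values of named genes under the alternatives other than leave-one-out, 10984 kept their side of the threshold (122 of them changed sign, called in neither fit), 458 lost their call, 127 gained one and 22 called values turned sign. Under leave-one-out 17054 of 17424 were kept, 335 lost their call, 35 gained one and 0 called values turned sign; 71 of those kept changed sign without a call.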

Other observations

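Tests in this part were all set before their results were seen. Of 13 immediate early and dissociation genes, 3 rose and 5 fell at 10 days, 0 rose and 5 fell at 4 weeks, 2 rose and 2 fell at 12 weeks and 0 were called at 20 weeks. Under median centring Fosb (0.07) and Dnajb1 (0.15), called lower at 12 weeks, lay above 0. The list median at 12 weeks was then 1.085 in place of -0.07. The heat shock genes Hspa1a and Hspa1b rose at 10 days (1.80 ± 0.59 and 1.49 ± 0.43, SD, n = 6) and at 12 weeks (1.501 ± 0.469 and 1.44 ± 0.36), while Fos (-1.07 ± 1.15), Egr1 (-1.16 ± 0.77) and Dnajb1 (-1.60 ± 0.78) fell at 4 weeks. The list was not called at any age.

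Adenosine signalling genes moved singly. Adora2a, a receptor that restrains immune cells, rose at 4 weeks (1.55 ± 0.35), Adora2b fell at 12 weeks (-1.23 ± 0.31), and the nucleoside transporter Slc29a1 fell from 10 days to 20 weeks (-1.32 ± 0.16, SE). Adora1, which alpha cells express, was -0.40 ± 0.43 at 20 weeks and not called. In Y-linked genes, a check of the mice's labelled sex, 0 signals of 6 probes of 4 genes were above background on the 24 arrays.

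Among the 20 week mice the beta cell mean ran from -2.28 to -0.61, and the hypothesis was that it falls as infiltrating or exocrine cells rise. It was tested in 4 relations over 6 mice. Pearson's r was 0.85 with the T cell mean (permutation p = 0.0361, adjusted p = 0.05), and Spearman's rho was 0.49 (permutation p = 0.356, adjusted p = 0.474). Without the 2 mice farthest from the median of the T cell mean, r was 0.86. In each relation the 2 mice left out were chosen by the other list, not by the beta cell mean. No relation was computed with only replicate 5 left out, the dimmest NOD sample, in which Ins1 read -5.11. Its part in these values of r was not tested. For the macrophage and dendritic cell mean r was 0.84 (permutation p = 0.0278, adjusted p = 0.05; rho 0.60, permutation p = 0.242, adjusted p = 0.474; r 0.85 without the 2 mice). For the acinar mean r was -0.83 (permutation p = 0.0375, adjusted p = 0.05; rho -0.60, permutation p = 0.242, adjusted p = 0.474; r -0.85 without the 2 mice). With the stellate cell mean r was 0.60 (permutation p = 0.221, adjusted p = 0.221; rho 0.26, permutation p = 0.658, adjusted p = 0.658; r 0.21 without the 2 mice). None passed the threshold of an adjusted p under 0.05, and the T cell, macrophage and stellate relations had the sign opposite to the hypothesis. The mice lay on 2 slides, 2 mice on one and 4 on the other, too few for a value within each.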
